A study of Mus musculus with 6 samples.

How the data were processed

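Total RNA (6 ug per sample) from J1 mouse embryonic stem cells was hybridized to Affymetrix Mouse Genome 430 2.0 arrays, 1 sample per array, per the labels' protocols. Cells were infected with pLKO.1 lentivirus, selected from 1 day after infection with puromycin at 1.5 ug/ml for 2 days, replated and cultured for 4 days on gelatin with 15% serum and 1000 U/ml leukemia inhibitory factor. The 6 samples form 3 groups of 2: shNT, shJmjd1c#3 (sh3) and shJmjd1c#4 (sh4), taken from the transfection label. The labels call the 2 samples of a group biological replicates and the series design speaks of independent duplicates. The replicate numbers come from the sample titles, and no source used here states a shared day. Deviations of same-numbered arrays from their group means correlated across genes at 0.223 to 0.302 in the 3 pairs of groups. The numbers were therefore taken to pair the samples, an inference from these same data that does not show shared preparation. Values with the replicate number as a block (the block, with residual df 2 and prior df 9.34) are given beside results whose call or count it changed. They depend on that pairing, because removing deviations found in the same arrays can lower the spread behind the tests.

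The deposited values are array signal intensity on a linear scale, made with MAS5 per the submitters' processing notes; the version is not given in the sources used here. The mean of the middle 96% of values was about 500 on every array, so the deposited signal had been scaled per array, and it was used as it stands. No background correction was added. The array held 45101 probe sets, of which 64 were controls. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none, and only the first kind was named. Of these, 34754 matched a current gene by Entrez ID, and 0 symbols changed. Signal near background carries little information on fold change. A bacterial control absent from the samples read at most 27.8 over the 6 arrays, on sh3 replicate 1, and 8.90 and 5.62 on the control arrays.

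Signals were transformed to log2(signal + 16). For each of the 18193 genes the probe set with the highest mean over the 6 arrays was kept, and genes with a mean at or above the 40th percentile of all probe sets without controls (log2 5.81, a signal of 40.12) were tested, 12684 in all. Fold changes are on the log2(signal + 16) scale, which understates the change of dim genes. Limma 3.58.1 in R 4.3.3 fitted 3 group means over all 6 arrays (residual df 3, prior df 5.96), with empirical Bayes moderation along the intensity trend, 2-sided tests and Benjamini-Hochberg adjustment at 0.05 over all genes tested. The contrasts were the mean of both hairpins against shNT (the knockdown mean), each hairpin against shNT, and sh4 minus sh3. The probe sets of Jmjd1c were tested in the same fit over all probe sets without controls and with no filter. Errors of signals are SDs over arrays and errors of log2 values are standard errors from limma.

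The gene lists, 29 in number, were written before the data were examined, as were the design, the rule for named genes and the alternatives other than those said to be added. They covered pluripotency, primed or formative epiblast, primitive streak, mesoderm, endoderm, neuroectoderm, trophectoderm, epithelial junction, mesenchymal, ERK response, FGF receptor to ERK cascade, Wnt target, Nodal and BMP target, miR-200 target, miR-290 and miR-302 target, germline, 2-cell-like, interferon, p53, cell cycle, ATF4 and ER stress, cholesterol synthesis, glycolysis and hypoxia, H3K9 methylation, imprinted, feeder fibroblast, extracellular matrix, ribosomal protein and housekeeping genes. The 28 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with camera's estimated correlation and with fry, which asks whether a list's genes move 1 way without comparing them with other genes. No list kept its camera call with an estimated correlation in any contrast. A gene is said to rise or fall when its limma test passed over all genes, or adjusted over the list alone where that is said, and a list when its camera test with the preset correlation passed.

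Named genes are Jmjd1c and the 12 largest rises and 12 largest falls among genes past the threshold in the knockdown mean with all 4 knockdown arrays on 1 side of both controls. For each list up to 4 members with the smallest p were named, for each hairpin the 3 largest rises and falls among calls, and for the difference between hairpins the 6 largest each way, filled up by smallest p as values. Genes with a RIKEN or Gm symbol were passed over. The correlation and overlap of the hairpins were set beside simulations of unchanged groups against the same controls.

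The pipeline was tested on simulated data with 200 changed genes among 12684, in 20 runs of the knockdown mean. It recovered 35.6% of genes changed 1.5-fold, 71.8% at 2-fold and 96.0% at 4-fold, with a false share of 7.57% of calls. With no change the median number of calls was 0 and 0.1 lists were called per run, and a list shifted by 0.3 was called in 20 of 20 runs. With the block, 20 simulations of unchanged groups gave a median of 0 and at most 2 calls in the knockdown mean. All these simulations drew noise independently for each gene and array, without correlation between genes or a shared replicate effect. Their rates of false calls and false lists need not hold for the real arrays.

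Alternatives were a pseudocount of 1 or 64, no filter or the 60th percentile, quantile normalization, median centring, the mean of a gene's probe sets, no probe sets ending in _s_at or _x_at, no trend, robust moderation, the replicate number as a block, each array left out in turn, 4 knockdown arrays as 1 group, only the 4 arrays compared, and the other list tests. Added after the data were seen were gene families by symbol stem, every probe set tested by itself, the mesenchymal list without feeder markers, and the comparisons of the hairpins within replicate numbers. An array group left with 1 array was assumed to vary like the other groups.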

Results

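Gene expression was profiled in J1 cells, a mouse embryonic stem cell line, kept on gelatin with serum and leukemia inhibitory factor, the cytokine that holds such cells undifferentiated. The cells carried a lentiviral short hairpin RNA: a non-targeting control (shNT), or 1 of 2 hairpins against Jmjd1c, shJmjd1c#3 and shJmjd1c#4, called sh3 and sh4 here. Jmjd1c encodes a JmjC-domain protein of the histone lysine demethylase family. Each of the 3 groups had 2 arrays, from biological duplicates per the labels, so 6 arrays were compared, and their number limits the precision. The median signal of an array lay between 69.3 and 81.3, and 43.96% to 46.24% of probe sets exceeded a signal of 100. Across genes, which are not independent replicates, the 2 arrays of a group correlated at r = 0.978 in shNT, 0.986 in sh3 and 0.980 in sh4, and arrays of different groups at 0.969 to 0.984. The ratio of 3' to 5' Actb signal, a measure of RNA integrity, was 2.73 ± 0.0495 in shNT, 2.33 ± 0.101 in sh3 and 2.80 ± 0.00636 in sh4 (SD, n = 2 each). The 18S ribosomal RNA control probe set read 8140 and 6875 in the control arrays, 6177 and 5333 in sh3, and 3712 and 5013 in sh4. Its mean log2 difference, knockdown minus control, was -0.59, and -0.58 and -0.60 with quantile normalization and median centring. The 18S signal was thus lower in every knockdown array than in both controls, and this stood beside the group changes of the knockdown mean given below.

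The targeted gene was measured first. The most abundant of its 3 probe sets, 1426900_at, read 5788 ± 385 in shNT, 4763 ± 313 in sh3 and 3744 ± 666 in sh4 (SD, n = 2 each), and all 4 knockdown arrays lay below both controls. The knockdown mean was 72.8% of control, with 82.3% in sh3 and 64.4% in sh4. On the log2 scale the difference was -0.46 (SE 0.13; adjusted p = 0.358 by limma with Benjamini-Hochberg over all probe sets), which did not pass the threshold. Neither sh3 nor sh4 passed by itself (adjusted p = 0.778 and 0.281 by limma). The difference sh4 minus sh3 was -0.36 (SE 0.15, adjusted p = 0.946 by limma), so a deeper knockdown by sh4 was not shown. The other probe sets had higher values in the knockdown arrays, and at each of them all 4 knockdown arrays lay above both controls. Probe set 1448049_at read 371 ± 3.09 in shNT, 694 ± 47.6 in sh3 and 726 ± 136 in sh4, a log2 difference of 0.90 (SE 0.15, adjusted p = 0.118 by limma), which passed with the replicate number as a block (SE 0.129, adjusted p = 0.0127 by limma). Probe set 1439998_at read 235 ± 53.2, 399 ± 160 and 412 ± 21.4, a log2 difference of 0.73 (SE 0.25, adjusted p = 0.439 by limma). The positions of these probe sets relative to the hairpin targets were not analysed here. No probe set passed without the block, the 1 that passed with it was higher, and they disagreed in direction, so the groups are called knockdown here by their labels.

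**Figure D1:**
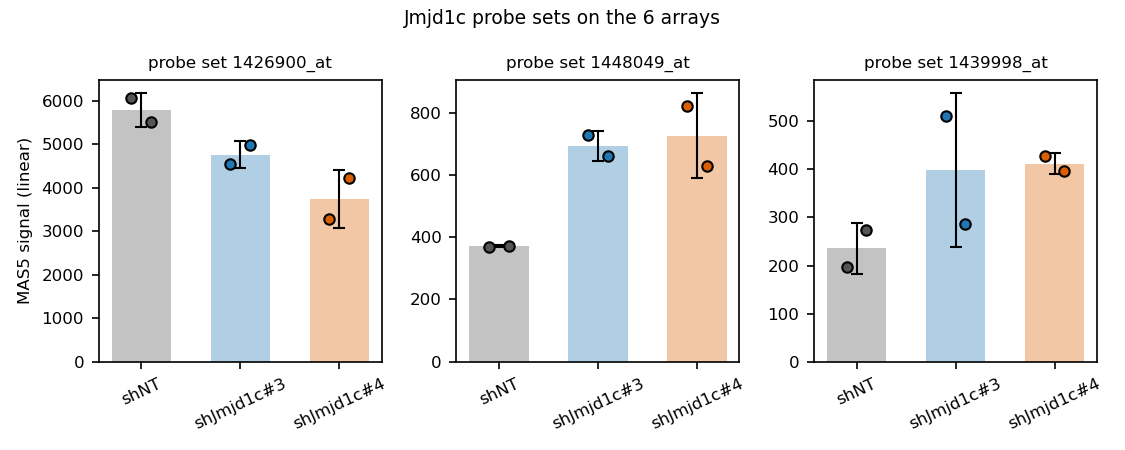
MAS5 signal (linear scale) of the 3 Jmjd1c probe sets in shNT, sh3 and sh4, with bars at the group mean, error bars of 1 SD and points for the 2 arrays of each group. At 1426900_at the group means were 5788, 4763 and 3744, while 1448049_at and 1439998_at had higher means in both knockdown groups than in shNT.

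The main comparison asked which genes differed between knockdown cells, as the mean of both hairpins, and control cells. Tnc, which encodes the matrix glycoprotein tenascin C, rose from a signal of 13.0 ± 9.38 to 241 ± 108 (SD, n = 2 control and 4 knockdown arrays; log2 3.09, SE 0.27, adjusted p = 0.00876 by limma). Acta2, smooth muscle actin, rose from 748 ± 231 to 3070.03 ± 640 (log2 2.03, SE 0.22, adjusted p = 0.0117 by limma), and Col3a1, a fibrillar collagen, from 31.6 ± 8.47 to 181 ± 59.6 (log2 2.01, SE 0.30). Flnc, an actin cross-linking filamin, rose by a log2 of 1.67, and Antxr2, a receptor that binds collagen, by 2.26. Cdx2, a homeobox factor of trophectoderm and posterior embryo, rose from 10.6 ± 11.6 to 131 ± 53.4 (log2 2.47, SE 0.40), and Prickle1, a planar cell polarity gene, from 463 ± 57.2 to 1715 ± 493 (log2 1.81, SE 0.13, adjusted p = 0.00242 by limma). Megf10, an engulfment receptor, rose by 2.32, Il33, a cytokine, by 1.72, Spred3, of a family of ERK pathway inhibitors, by 1.91, Pkdcc, a secreted kinase, by 1.64, and Aadat, an aminotransferase, by 2.00. The control means of Tnc, Cdx2, Megf10, Antxr2, Col3a1, Aadat and Spred3 lay below the filter signal of 40.12, so their fold changes and their order depend on the pseudocount. With a pseudocount of 64 these 7 were at 1.92, 1.36, 1.27, 1.28, 1.33, 1.03 and 1.05, and with a pseudocount of 1 Cdx2 was at 3.92 and Aadat at 3.23.

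Nupr1, a stress-induced transcriptional regulator, fell from a signal of 1313 ± 476 to 454 ± 51.7 (SD, n = 2 control and 4 knockdown arrays; log2 -1.46, SE 0.21, adjusted p = 0.0279 by limma). Prdm1, a repressor needed for primordial germ cells, fell from 905 ± 129 to 359 ± 68.0 (log2 -1.31, SE 0.18, adjusted p = 0.0225 by limma). Dppa3, also called Stella, a gene of naive embryonic stem cells and germ cells, fell from 2649 ± 419 to 1372 ± 137 (log2 -0.94, SE 0.14). Aurkc, the Aurora kinase of meiosis, fell by 0.99 on the log2 scale. Gli1, a transcription factor and target of Hedgehog signalling, changed by -1.12, Pdgfc, a growth factor, by -1.02, Lgals3, galectin-3, by -1.08 and Adgre5, an adhesion receptor, by -0.98. Cdyl2, which encodes a chromodomain protein, fell from a signal of 5183 to 2634. Mep1b, a metalloprotease, changed by -1.14, Phf11d by -1.04 and Fam25c by -1.01.

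In all, 92 of 12684 genes passed the adjusted threshold in the knockdown mean by limma, 71 higher and 21 lower, against 1559 genes with an unadjusted p under 0.05. Of these calls 43 were higher and 9 lower by at least 2-fold, and in all 92 the 4 knockdown arrays lay on 1 side of both controls. With the replicate number as a block 710 genes passed by limma, 423 higher and 287 lower, of which 106 and 24 by at least 2-fold, and all 92 were among them. Counts with the block hold only if same-numbered samples belong together, which no label states. The median control signal was 472.4 for genes that rose and 1332 for genes that fell, and 9 of the 71 rises started from a control mean below the filter signal. The count depended on single arrays, with 43 calls without control 1, 4 without control 2, 26 and 10 without sh3 replicates 1 and 2, and 8 and 41 without sh4 replicates 1 and 2. It was 0 by limma without an intensity trend (1499 genes with an unadjusted p under 0.05), 36 without the filter on dim probe sets, 34 with the mean of a gene's probe sets and 59 without probe sets that may cross-hybridize. All 24 named genes kept their direction without each array, which the rule for naming them, with no overlap of arrays, fixed in advance. Only Tnc, Acta2 and Prickle1 stayed past the threshold each time, and Aadat, Spred3, Mep1b, Gli1 and Aurkc never did. With the mean of a gene's probe sets Acta2 and Prickle1 were lost at 0.67 and 0.69 (adjusted p = 0.309 and 0.2215 by limma), Cdyl2 at -0.40 (0.394), and Tnc stayed at 1.86 (0.0469). Without probe sets that may cross-hybridize Flnc was lost at 1.06 (adjusted p = 0.122 by limma). Acta2 and Pkdcc were not tested in that setting, because none of their remaining probe sets passed the filter. Of the 24, calls lost numbered 24 without a trend, 11 without the filter, 6 of the 23 tested with the mean of probe sets, 3 of the 22 tested without probe sets that may cross-hybridize, 3 each with a pseudocount of 1 and with quantile normalization, 2 with the knockdown arrays as 1 group and 1 with a pseudocount of 64. A 60th percentile filter left 7 of the 24 untested and kept the calls of the other 17. Per array left out, 11 (control 1), 3 (control 2), 11 and 5 (sh3), and 3 and 13 (sh4) of the 24 stayed past it. Among 40 called genes examined, 20 had another probe set above the filter; 29 of these 31 probe sets had the same sign, and 1 each for Cdyl2 (0.25, SE 0.33) and Sparc (-0.26, SE 0.28) had the opposite one.

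**Figure D2:**
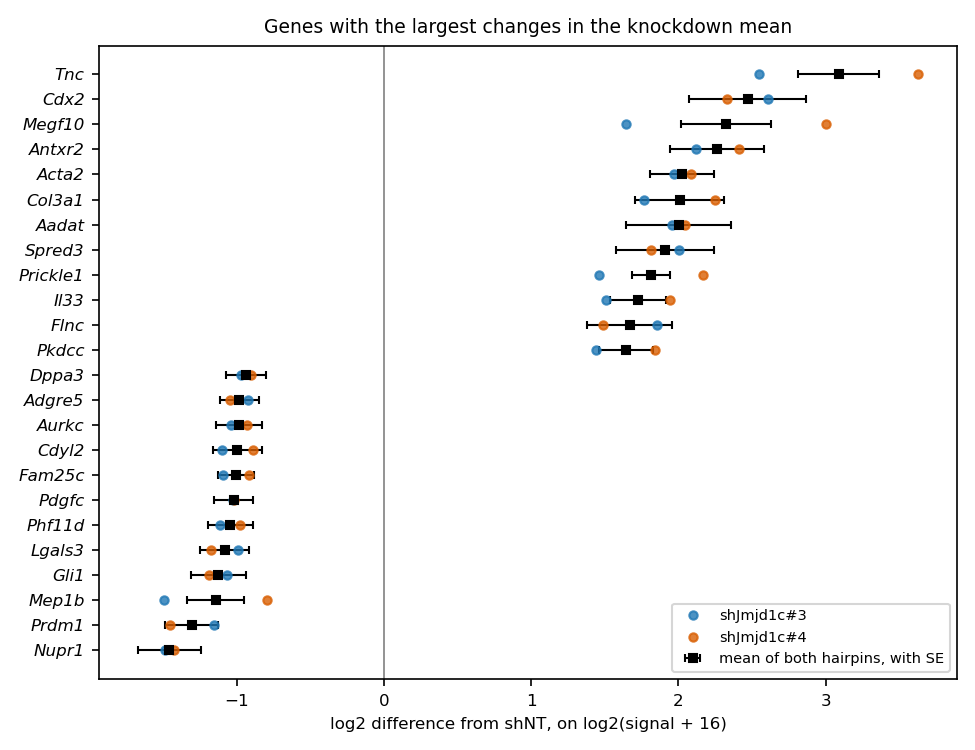
Log2 difference from shNT of the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with coloured points for each hairpin and black squares with SE bars for the mean of both. Values of the mean run from 3.09 for Tnc to -1.46 for Nupr1.

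In the knockdown mean 13 lists passed by camera. Of these, 5 also passed by fry (adjusted p of 0.0122 to 0.0202): mesenchymal, mesoderm, endoderm, ERK response and feeder genes. Pluripotency, primed epiblast, germline, neuroectoderm, ATF4, extracellular matrix, imprinted and ribosomal genes did not (fry adjusted p of 0.0547 to 0.66). With the block 11 lists passed by fry. Mesenchymal genes rose as a group in the knockdown mean. The median of 25 tested genes was 0.64 on the log2 scale (camera adjusted p = 6.07e-11; adjusted p = 0.139 with an estimated correlation). Of the 25, 6 rose by limma over all genes, 15 rose and 1 (Zeb1, an E-box repressor, log2 -0.51) fell adjusted over the list alone. With the block 12 rose over all genes, and 16 rose and 2 fell adjusted over the list alone. Tagln, transgelin, rose by 1.55 and Sparc, a secreted matrix protein, by 0.64, beside Tnc and Acta2. Vim, vimentin, rose by 1.05 and Cald1, caldesmon, by 0.81; both were chosen after their values were seen. Without 1 array, Vim was called only without control 1 (log2 1.39) and Cald1 only without sh3 replicate 1 (0.91), Zeb1 was at -0.34 without control 2, and 2 to 4 of the 25 rose over all genes. Extracellular matrix and integrin genes had a median of 0.19 over 26 genes (camera adjusted p = 0.000722; adjusted p = 0.354 with an estimated correlation). The basement membrane collagen Col4a1 rose by 1.13, the collagen chaperone Serpinh1 by 1.24 and Sparc by 0.64, and 7 rose and 1 fell (Nid1) adjusted over the list alone. With the block 7 rose and 1 fell over all genes, and 10 rose and 2 fell adjusted over the list alone. Over all genes, leaving out 1 array left 0 to 2 extracellular matrix genes, 0 to 2 endoderm genes and 0 to 4 neuroectoderm genes higher by limma, and 0 to 1 each of the ERK response, imprinted and feeder genes. Without control 1 the extracellular matrix call was lost (median 0.24, camera adjusted p = 0.0557). Mesoderm genes had a median of 0.36 over 17 genes (camera adjusted p = 0.000686; adjusted p = 0.156 with an estimated correlation), with Acta2 past the threshold over all genes and 2, Acta2 and cardiac actin Actc1 (log2 1.09), adjusted over the list alone. Twist1 (log2 0.78, and 0.51 with a pseudocount of 64) and Flt1 (log2 1.21) were not past it, and Flt1 was at 1.99 without control 1, 0.42 without control 2 and 0.74 with a pseudocount of 64. With the block 2 rose over all genes, Actc1 being the other (adjusted p = 0.00852 by limma), and 7 adjusted over the list alone. Adjusted over the list alone 4 rose without control 1 and 1 without control 2. With a 60th percentile filter the mesoderm call was lost (camera adjusted p = 0.0679).

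Markers of feeder fibroblasts, a cell type often used to support embryonic stem cells, moved with these groups. All 15 tested markers were positive, with a median of 0.56 (camera adjusted p = 2.57e-05, and 0.139 with an estimated correlation), and 13 and 14 of the 15 were positive in sh3 and sh4. Of 23 listed markers only these passed the filter, which used the mean of all 6 arrays and so favoured dim markers that rose. Col3a1 and Dcn had control means of 31.6 and 11.3, below the filter signal, while Postn (log2 -0.35) and Lum (0.75) were left out. The filter may thus add to the agreement in sign. Col3a1 rose over all genes, and Col3a1 and the proteoglycan gene Dcn (log2 1.67) rose adjusted over the list alone, while Col5a1 (log2 0.56) and Twist1 (log2 0.78) did not. With the block Dcn also rose over all genes (adjusted p = 0.018 by limma), and 7 rose adjusted over the list alone. Dcn was at 0.86 with a pseudocount of 64, and 4 rose adjusted over the list alone without control 2. Their levels were mostly low: Col1a1 read 39.5 in control and 65.6 in knockdown arrays, Col1a2 114 and 199.9, and Dcn 11.3 and 77.0. Controls 1 and 2 read 5.88 and 73.2 for Col1a1, and 52.1 and 175.8 for Col1a2. For both genes control 2 lay within the range of the knockdown arrays, while for Dcn both controls lay below it. The most abundant marker, Fstl1, read 1797.5 and 2218.2. Of the 15 markers, 11 had a control mean above the filter signal, and 2 were also members of the mesenchymal list and 1 of the mesoderm list. Without those 2, a test added after the data were seen, the mesenchymal list of 23 genes had a median of 0.64 (camera adjusted p = 1.49e-10).

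Pluripotency genes fell as a group by camera, but did not pass by fry (adjusted p = 0.185, and 0.0446 with the block). Over 27 genes the median was -0.30, with 23 negative (camera adjusted p = 2.11e-08; adjusted p = 0.354 with an estimated correlation). Dppa3 alone fell over all genes, and 8 fell adjusted over the list alone, among them the naive-state factor Klf4 (log2 -0.55), the cofactor Tcl1 (log2 -1.21) and Jam2 (log2 -0.96). The core factors Pou5f1 (log2 -0.04, SE 0.12) and Nanog (log2 -0.40, SE 0.18), chosen after their values were seen, were not past the threshold by limma, with adjusted p of 0.934 and 0.425. With the block 13 fell over all genes, with Klf4, Tcl1, Jam2 and Nanog among them (adjusted p = 0.00547, 0.000383, 0.00144 and 0.0151 by limma), and 18 fell and 1 rose adjusted over the list alone. Nanog was at -0.70 without control 1 and -0.09 without control 2. Adjusted over the list alone 13 fell without control 1, 1 without control 2, 3 without sh3 replicate 1 and 4 without sh4 replicate 1. The median was -0.48 without control 1 and -0.18 without control 2. Primed or formative epiblast genes, expressed after the naive state, had a median of 0.47 over 16 genes (camera adjusted p = 0.000248; adjusted p = 0.446 with an estimated correlation). None passed over all genes, and 3 rose adjusted over the list alone: Fgf5 (log2 2.08), Pou3f1 (log2 1.15) and Cldn6 (log2 0.61), while Sox4 (log2 0.51) did not. With the block 10 rose over all genes, these 4 included (adjusted p = 0.00142, 0.000218, 0.0341 and 0.0053 by limma), and 12 adjusted over the list alone. Pou3f1 was at 0.67 without control 2, Sox4 at 0.80 without control 1 and 0.22 without control 2, and Fgf5 at 1.24 with a pseudocount of 64. Adjusted over the list alone 7 rose without control 1, 0 without control 2 and 1 without sh3 replicate 1 or sh4 replicate 1. Without control 1 this median was 0.72, and without control 2 the call was lost (median 0.15, camera adjusted p = 0.12). Germline genes fell as a group, with a median of -0.25 over 23 genes (camera adjusted p = 0.000722; adjusted p = 0.354 with an estimated correlation). The meiotic cohesin gene Stag3 (log2 -0.94) fell adjusted over the list alone and 0 of the 23 passed over all genes by limma; Tex14, Syce1 and Sycp3 were at -0.78, -0.43 and -0.36. With the block 3 fell over all genes, Stag3 and Tex14 among them (adjusted p = 0.000719 and 0.00769 by limma), and 7 adjusted over the list alone. Of the germline genes 3 fell adjusted over the list alone without sh4 replicate 2, and Stag3 was no longer past it without control 2, sh3 replicate 1 or sh4 replicate 1. The germline median was -0.16 both without control 2 and without sh4 replicate 1.

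Endoderm and neuroectoderm genes rose as groups. The lists share members, so their shifts are not independent. Col4a1, Col4a2 and Sparc are also on the extracellular matrix list, Cdh2 and Sparc on the mesenchymal list, and Fgf5 on both the primed epiblast and ERK response lists. Acta2 is on both the mesoderm and mesenchymal lists. For endoderm the median was 0.36 over 22 genes (camera adjusted p = 0.000162; adjusted p = 0.139 with an estimated correlation). Col4a1 (log2 1.13), the endocytic receptor Lrp2 (log2 1.18) and Sparc (log2 0.64) rose over all genes, and 9 rose, Col4a2 (log2 1.06) included, and 2 fell (Hnf4a and Apoe) adjusted over the list alone. With the block 8 rose, Col4a2 included (adjusted p = 0.00539 by limma), and 2 fell over all genes. Adjusted over the list alone 4 rose without control 2, 5 without sh3 replicate 1 and 6 without sh4 replicate 1. The endoderm median was 0.22 without sh3 replicate 2. For neuroectoderm the median was 0.31 over 16 genes (camera adjusted p = 0.00303; adjusted p = 0.354 with an estimated correlation). Nes, the intermediate filament nestin, rose by 1.37 over all genes, and 5 rose adjusted over the list alone, among them N-cadherin Cdh2 (log2 1.17), Gbx2 (log2 1.14) and Sox11 (log2 0.77). With the block 5 rose, these 3 included (adjusted p = 0.000458, 0.00766 and 0.0053 by limma), and 1 fell over all genes, and 5 rose and 2 fell adjusted over the list alone. Cdh2 was at 0.70 and Sox11 at 0.41 without control 2, when 2 rose adjusted over the list alone. Without control 2 the neuroectoderm call was lost (median 0.15, camera adjusted p = 0.0701).

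ERK response and feedback genes rose, with a median of 0.25 over 28 genes (camera adjusted p = 0.000146; adjusted p = 0.139 with an estimated correlation). The ERK phosphatase Dusp6 (log2 0.80) and the AP-1 subunit Jun (log2 0.83) rose over all genes, and 6 rose adjusted over the list alone, among them Fgf5 (log2 2.08) and Spred1 (log2 0.57). With the block 7 rose, these 2 included (adjusted p = 0.00142 and 0.00803 by limma), and 1 fell over all genes. Imprinted genes had a median of 0.25 over 24 genes (camera adjusted p = 0.00303; adjusted p = 0.207 with an estimated correlation), with Peg3 (log2 0.70) and Plagl1 (log2 1.07) past the threshold over all genes and 7 higher, Mirg (log2 0.80) and Rian (log2 0.49) included, and 1 lower (Igf2r) adjusted over the list alone. With the block 8 rose, Mirg and Rian included (adjusted p = 0.00767 and 0.0142 by limma), and 1 fell over all genes. Without control 2, 4 imprinted genes were higher adjusted over the list alone. The imprinted call was lost without control 1 (median 0.18, camera adjusted p = 0.115). ATF4 and ER stress genes fell, with a median of -0.25 over 25 genes (camera adjusted p = 2.57e-05; adjusted p = 0.164 with an estimated correlation). Nupr1 fell over all genes, and 3 fell adjusted over the list alone, namely Nupr1, the pseudokinase Trib3 (log2 -0.58) and the ER co-chaperone Dnajc3 (log2 -0.45); Slc7a5 was at -0.36. With the block 6 fell over all genes, Trib3, Dnajc3 and Slc7a5 included (adjusted p = 0.018, 0.0364 and 0.0132 by limma), and 11 fell and 1 rose adjusted over the list alone. Adjusted over the list alone 8 fell without control 1, 2 without sh4 replicate 1 and 1 without control 2, either sh3 array or sh4 replicate 2. Ribosomal protein genes had a median of -0.12 over 20 genes (camera adjusted p = 0.0172; adjusted p = 0.634 with an estimated correlation), and 0 passed by limma, over all genes or adjusted over the list alone, with Rps9 at -0.19 (-0.41 without control 1, 0.03 without control 2) and Rps6 at 0.18 (0.29 and 0.08, and 0.12 without sh3 replicate 2). The ribosomal median was -0.32 without control 1, turned to 0.07 without control 2 (camera adjusted p = 0.124), and the call was also lost without sh3 replicate 1 (0.149), without sh4 replicate 1 (0.194), with quantile normalization (0.498), a 60th percentile filter (0.0507), the mean of probe sets (0.111), no trend (0.0592) and no probe sets that may cross-hybridize (0.103). Without sh3 replicate 1 and sh4 replicate 1 it was -0.08 and -0.07.

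The other 15 lists tested did not pass in the knockdown mean by camera. For trophectoderm genes the median was 0.20 (camera adjusted p = 0.167); Cdx2 rose over all genes, and Cdx2 and Fgfr2 (log2 0.78) adjusted over the list alone. Epithelial junction genes were at 0.12 (camera adjusted p = 0.0698), with E-cadherin Cdh1 at 0.24 (SE 0.10), and at 0.13 without control 2. Primitive streak genes were at -0.05 (camera adjusted p = 0.172) with 2, Lefty2 (log2 -1.07) and Nodal (log2 -0.48), lower adjusted over the list alone. Nodal and BMP targets were at 0.03 with the camera test pointing down (adjusted p = 0.868); adjusted over the list alone 1, Id3 (log2 0.80), was higher and 3, with Lefty1 (log2 -0.70), were lower. Camera adjusted p was 0.275 for FGF receptor to ERK cascade components (median 0.05), 0.167 for Wnt targets (0.14, with Cdx2 past the threshold), 0.139 for miR-200 targets (0.10, with Ets1 at 1.51) and 0.806 for miR-290 and miR-302 targets (0.04 with the test pointing down, and Lats2 at 1.25). It was 0.732 for interferon genes (0.03 with the test pointing down, and Ifitm3 at -0.56), 0.912 for p53 targets (-0.02 with the test pointing up), 0.164 for cell cycle genes (-0.06) and 0.322 for cholesterol synthesis genes (0.09, with Idi1 at 0.84). It was 0.372 for glycolysis and hypoxia genes (-0.0025, with Pfkp at -0.60), 0.255 for H3K9 methylation enzymes and readers (-0.06, with Cbx3 at -1.43 and Kdm3a, a relative of Jmjd1c, at -0.26) and 0.349 for housekeeping genes (-0.05). Of 21 listed 2-cell-like genes 4 were above the filter, with a median of 0.05, and no test was made. Leaving out 1 array brought 4 of these lists past the threshold by camera: trophectoderm without sh3 replicate 1 (0.0343), epithelial without sh3 replicate 1 (0.018) or sh4 replicate 2 (0.031), cholesterol without control 1 (0.00671) and glycolysis without control 2 (0.00105). A 60th percentile filter did so for epithelial genes (0.0365) and the mean of probe sets for miR-200 targets (0.0134).

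With the replicate number as a block, epithelial junction genes passed in the knockdown mean too (camera adjusted p = 0.017; adjusted p = 0.52 with an estimated correlation), so 14 lists did. Of the 34, 4 then rose over all genes by limma and 8 adjusted over the list alone. Among trophectoderm genes 5 rose and 1 fell over all genes, Fgfr2 among the former (adjusted p = 0.0284 by limma). Of the other genes named for these 15 lists, Lefty2, Nodal, Lefty1, Ifitm3 and Cbx3 then fell (adjusted p = 0.000218, 0.00847, 0.000586, 0.00803 and 0.0496 by limma) and Id3 rose (adjusted p = 0.0083). Without controls 1 and 2 Id3 was at 0.37 and 1.24, Lefty1 was at -0.41 without control 1, and Cbx3 at -0.88 with a pseudocount of 64. Primitive streak genes had 0 higher and 2 lower over all genes, and Nodal and BMP targets 1 higher and 3 lower.

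**Figure D3:**
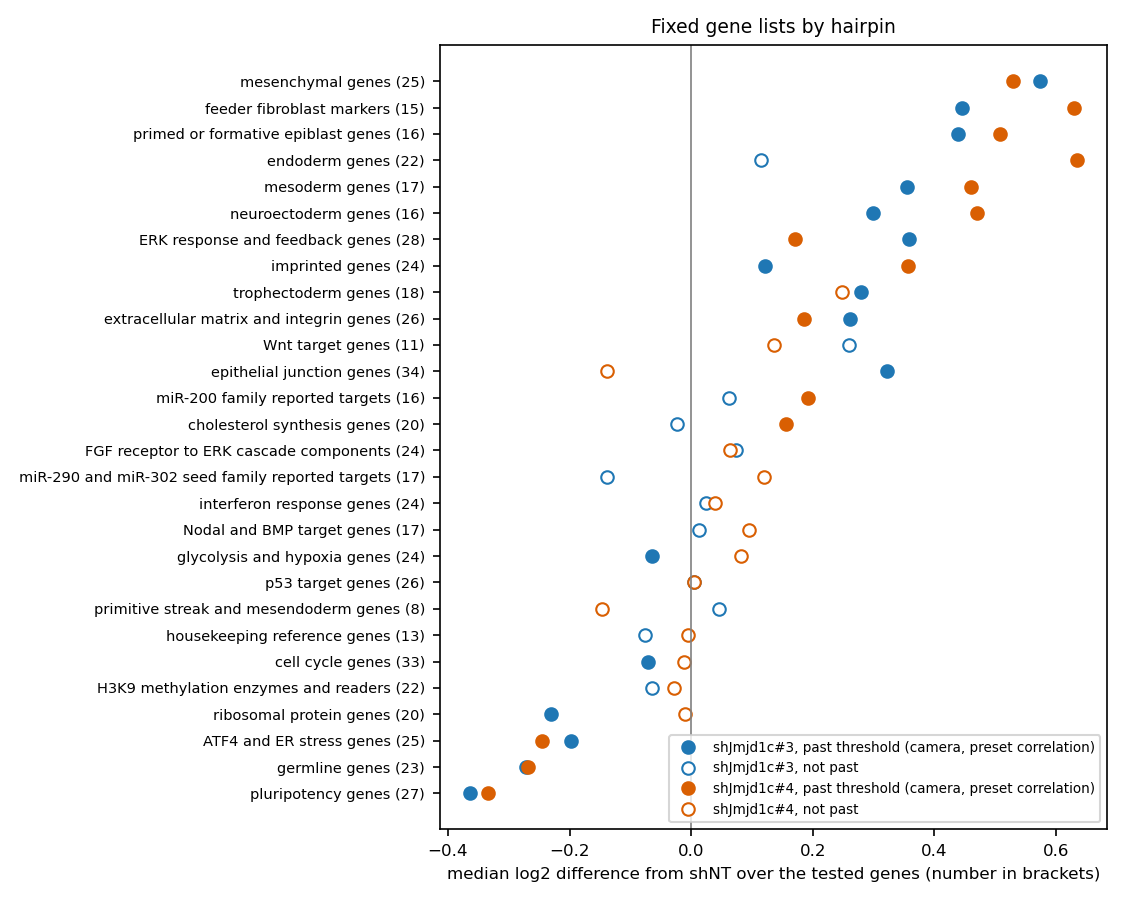
Median log2 difference from shNT of each gene list, 1 symbol per hairpin, filled where the list passed the adjusted threshold by camera with a preset correlation. The mesenchymal list, at 0.57 in sh3 and 0.53 in sh4, and the pluripotency list, at -0.36 and -0.33, were filled for both hairpins.

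Each hairpin was then compared with the control by itself. With sh4, 46 genes passed by limma, 36 higher and 10 lower (1541 with an unadjusted p under 0.05), and 622 with the replicate number as a block, 341 higher and 281 lower. Tnc (log2 3.63, SE 0.32), Megf10 (3.00, SE 0.35) and Antxr2 (2.41, SE 0.37) rose, and Prdm1 (log2 -1.46, SE 0.21), Plac8 (-1.27, SE 0.17) and Dmrt1, a germline transcription factor (-1.21, SE 0.15), fell, with adjusted p of 0.00505, 0.0169, 0.0425, 0.0314, 0.0232 and 0.0216 by limma. Tnc, Megf10 and Antxr2 had control means of 13.0, 8.83 and 14.8, below the pseudocount of 16, so their size and order depend on it. An absent control read 8.90 and 5.62 on the control arrays and up to 27.8 on the knockdown arrays. With a pseudocount of 64 Tnc, Megf10 and Antxr2 were at 2.37, 1.76 and 1.39, and with 1 Antxr2 was not past the threshold (adjusted p = 0.0623 by limma). With sh3, 9 genes passed by limma, 8 higher and 1 lower (1235 with an unadjusted p under 0.05), and 435 with the block, 258 higher and 177 lower. The matrix gene Tnc (log2 2.55, SE 0.32), Acta2 (1.97) and Prickle1 (1.46) rose and Fam25c fell (log2 -1.10, SE 0.14), with an adjusted p of 0.0454 by limma for each. With a pseudocount of 64 Tnc was at 1.47 in sh3 and not past the threshold (adjusted p = 0.0557 by limma). All 9 sh3 calls and 38 of the 46 sh4 calls were also calls in the knockdown mean. The knockdown mean averages these same contrasts, so this overlap is partly built in. For sh4 the count was 39 and 5 without controls 1 and 2, 37 and 26 without sh3 replicates 1 and 2, and 3 and 20 without sh4 replicates 1 and 2. It was 6 without a trend, 21 without a filter and 27 with the mean of a gene's probe sets. For sh3 it was 1 without control 2 and 0 by limma without each other array, where 668 to 1705 genes had an unadjusted p under 0.05. It was 0 by limma also with a pseudocount of 1, without a filter, with a 60th percentile filter, with the mean of a gene's probe sets, without a trend and in a fit of only the 4 arrays compared, with 1022 to 1543 such genes. The share of higher calls for sh3 was 88.89%, and 100% (7 of 7) with median centring.

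By list, 16 passed in sh3 and 14 in sh4 by camera, 11 of them in both, and 0 with an estimated correlation in either. The lists of both hairpins were mesenchymal, extracellular matrix, mesoderm, feeder marker, primed epiblast, neuroectoderm, ERK response and imprinted genes, all higher, and pluripotency, germline and ATF4 genes, all lower. Of these, 4 passed in both hairpins without each array: pluripotency, mesoderm, mesenchymal and ERK response genes. In sh3, primed epiblast genes (camera adjusted p = 0.071), germline genes (0.0511) and ATF4 genes (0.0975) were lost without control 2, and feeder markers without control 1 (0.0721). Neuroectoderm genes were lost in sh3 without control 2 (camera adjusted p = 0.276) or sh3 replicate 1 (0.274), imprinted genes without control 1 (0.367) or sh3 replicate 2 (0.127), and extracellular matrix genes without the same 2 arrays (0.119 and 0.127). In sh4, primed epiblast genes were lost without control 2 (camera adjusted p = 0.259) or sh4 replicate 1 (0.263), germline genes without sh4 replicate 1 (0.205) and extracellular matrix genes without control 1 (0.0503).

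Other settings also ended calls of these lists. In sh4, ERK response genes were lost with the mean of probe sets (median 0.08, camera adjusted p = 0.0789) and mesoderm genes with a 60th percentile filter (0.36, 0.124). In sh3, feeder markers were lost with a 60th percentile filter (camera adjusted p = 0.0898), neuroectoderm genes with quantile normalization (0.0574) or no filter (0.146), and imprinted genes with the mean of probe sets (0.0877) or no trend (0.119). Medians that stayed past the threshold moved too. In sh4 the pluripotency median of -0.33 was -0.14 without control 2 and -0.15 without sh4 replicate 1, the ERK median of 0.17 was 0.06 without sh4 replicate 1, and the germline median of -0.27 was -0.52 without sh4 replicate 2. In sh3 the mesoderm median of 0.35 was 0.20 without control 2, and the primed epiblast median of 0.44 was 0.74 without control 1. Without sh3 replicate 1 the sh3 medians of primed epiblast, ATF4, imprinted and feeder genes went from 0.44, -0.20, 0.12 and 0.44 to 0.17, -0.13, 0.24 and 0.30. The neuroectoderm median in sh3, 0.30, was 0.51 without control 1 and 0.52 without sh3 replicate 2. With the mean of probe sets the medians of pluripotency genes were -0.23 in sh3 and -0.19 in sh4, of neuroectoderm genes 0.20 and 0.26, of ERK genes in sh3 0.24 and of miR-200 targets in sh4 0.33. With a 60th percentile filter the germline median was -0.38 in the knockdown mean and -0.43 in sh4, and the imprinted median 0.37 in the knockdown mean and 0.33 in sh3. With a pseudocount of 64 the feeder marker median was 0.35 in the knockdown mean and 0.26 in sh3, and without probe sets that may cross-hybridize the imprinted median in sh3 was 0.08.

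Past the threshold in sh3 and not sh4 were epithelial junction genes (median 0.32, camera adjusted p = 6.22e-08; adjusted p = 0.264 with an estimated correlation), ribosomal protein genes (-0.23, camera adjusted p = 2.42e-05; adjusted p = 0.421 with an estimated correlation) and 3 lists nearer the threshold. The latter were trophectoderm (0.28, camera adjusted p = 0.0446), cell cycle (-0.07, 0.0446) and glycolysis genes (-0.06, 0.0491), with adjusted p of 0.385, 0.321 and 0.618 with an estimated correlation. Past the threshold in sh4 and not sh3 were endoderm (0.63, camera adjusted p = 2.8e-06), miR-200 targets (0.19, 0.0429) and cholesterol synthesis genes (0.16, 0.0429), with adjusted p of 0.128, 0.316 and 0.623 with an estimated correlation. The difference between hairpins was not past the threshold by camera for trophectoderm (adjusted p = 0.273, and 0.0152 without sh3 replicate 1), cell cycle (0.28) and miR-200 genes (0.273); it was for the other 5 lists, as the comparison of sh4 with sh3 gives. With the block miR-200 targets were lost in sh4 (camera adjusted p = 0.0768), Wnt targets passed in sh3 (0.26, 0.0374) and primitive streak genes in sh4 (-0.15, 0.0461), the last 2 with adjusted p of 0.312 and 0.342 with an estimated correlation. This made 17 lists in sh3 and 14 in sh4, and 0 with an estimated correlation. Epithelial junction genes in sh3 and endoderm genes in sh4 passed without each array. Ribosomal genes in sh3 were lost without control 2 (median -0.05, camera adjusted p = 0.429) and with quantile normalization (-0.05, 0.141), and their median was -0.42 without control 1 and -0.13 without sh3 replicate 1. Trophectoderm genes were lost without control 1 (camera adjusted p = 0.263), sh3 replicate 2 (0.291) and sh4 replicates 1 and 2 (0.0632 and 0.0657), and under 5 other settings (0.0787 to 0.349). Cell cycle genes were lost without each array (camera adjusted p of 0.0523 to 0.218) and under 4 other settings (0.084 to 0.914). Glycolysis genes were lost without sh3 replicate 2 (camera adjusted p = 0.535) and sh4 replicates 1 and 2 (0.0596 and 0.0595), under 6 other settings (0.0512 to 0.162), and turned to a median of 0.15 without control 1 (0.648); the median was -0.19 without control 2 and 0.02 without sh3 replicate 2. In sh4, miR-200 targets were lost without control 2 (camera adjusted p = 0.111) and sh4 replicate 2 (0.154) and under 4 other settings (0.0515 to 0.171), with a median of 0.39 without control 1. Cholesterol genes in sh4 were lost without control 2 (camera adjusted p = 0.96) and sh4 replicate 1 (0.226) and under 3 other settings (0.0605 to 0.0934), with a median of 0.30 without control 1 and 0.29 without sh4 replicate 2. Some of these lists passed in the other hairpin in other settings: in sh3, endoderm genes with a 60th percentile filter (median 0.21, camera adjusted p = 0.0411) and cholesterol genes without control 2, in the opposite direction (-0.13, 0.0269), and in sh4, epithelial genes without sh4 replicate 1 (-0.18, 0.0305), glycolysis genes without control 1 (0.25, 0.027) and ribosomal genes without control 1 (-0.22, 0.000161) or control 2 (0.17, 0.000935). The Actb ratio of 3' to 5' signal, 2.33 in sh3, 2.73 in shNT and 2.80 in sh4, was lowest in sh3, beside these lists.

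The overlap of the hairpins was examined because both target the same transcript with different sequences. Both called Tnc, Acta2, Prickle1, B9d1, Greb1l and Prtg higher and Fam25c lower by limma. B9d1, a cilium transition zone gene, Greb1l, and Prtg, the early embryonic receptor protogenin, rose by 1.25, 1.24 and 1.23 in sh3, and were chosen after their values were seen. Efnb2, the ephrin-B2 ligand (log2 1.25), and Podxl, podocalyxin (log2 1.17), chosen likewise, were called in sh3 and not sh4, but their difference between hairpins was not past the threshold by limma (adjusted p = 0.827 and 0.658). With the block both passed in sh4 (adjusted p = 0.00106 and 0.00875 by limma). Independent lists would share 0.0227 higher and 0.000788 lower calls, and simulated unchanged groups against the same controls shared 0 on average in 20 simulations. With the block 152 higher and 82 lower calls were shared, 234 in all, where independent lists would share 6.94 and 3.92 and simulated unchanged groups 0. Both simulated values of 0 were nearly fixed in advance, because unchanged groups gave a median of 0 calls in the knockdown mean. They do not measure what the shared controls add. Across genes, the fold changes of the hairpins correlated at r = 0.664, against 0.498 in 100 simulations with no effect, and had a covariance of 0.0853 against 0.0334, a difference of 0.0519. Simulated with the spread left by the block the covariance was 0.0253 and the difference 0.0599. With a separate control array for each hairpin r was 0.224 or 0.163. With each hairpin taken from 1 replicate number and its own control, so that no array was shared, r was 0.235 or 0.239 and the covariance 0.0426 or 0.049, values added after the data were seen. The 2 control arrays were too few to split for the calls, so part of the excess of shared calls over independent lists may come from the shared controls. The 7 shared calls became 1 without control 2 and 0 without each other array.

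Without a variance model, 1421 genes (11.2%) had all 4 knockdown arrays above both controls and 1210 (9.54%) all below, where chance gives 6.67% each way, or 845.6 genes. Against the control of the same replicate number alone, a count added after the data were seen, 2391 genes (18.9%) were higher on all 4 knockdown arrays and 2081 (16.4%) lower, where chance gives 11.1% each way. Of the former counts, 136 were higher and 30 lower by at least 2-fold. Tnc, Acta2 and Prickle1 were among the higher genes and Nupr1 and Prdm1 among the lower, which the rule for naming them fixed in advance. Both directions together held 6527 genes without control 1 and 5805 without control 2, when a single control array was left and chance alone gives more.

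Last, sh4 was compared with sh3 directly. Epithelial junction genes, which encode adherens, tight and desmosomal junction proteins, were lower in sh4 than in sh3 in 33 of 34 cases (median -0.43, camera adjusted p = 1.56e-15; adjusted p = 0.261 with an estimated correlation). Against control, 31 of the 34 were higher in sh3 (median 0.32), and 13 were higher in sh4 (median -0.14, camera adjusted p = 0.112; -0.18 and 0.0305 without sh4 replicate 1). Adjusted over the list alone 5 were lower in sh4, the adaptor subunit Ap1m2 (log2 -0.81), desmoplakin Dsp (-0.60), Epcam (-0.45), claudin-7 Cldn7 (-0.79) and the protease St14 (-0.50), and 0 over all genes. With the replicate number as a block 20 were lower adjusted over the list alone and 3 over all genes, Ap1m2 among them (adjusted p = 0.0207 by limma). Endoderm genes were higher in sh4 (median 0.29, camera adjusted p = 0.000211; adjusted p = 0.261 with an estimated correlation), with 8 higher, Srgn, Col4a1, Cubn, Col4a2, Sox17, Lama1, Dab2 and Gata6, and 1 lower, Sparc, adjusted over the list alone; with the block 7 were higher over all genes, Srgn, Col4a1 and Cubn among them (adjusted p = 0.00112, 0.0219 and 0.0168 by limma). Members of both groups beyond 4 were named after their values were seen. Both calls were kept without each array, but the endoderm median was 0.18 without sh3 replicate 1, and 0.46 and 0.16 without sh4 replicates 1 and 2. The Actb ratio of 3' to 5' signal was 2.33 in sh3 and 2.80 in sh4, and the 18S signal was lower in both sh4 arrays than in both sh3 arrays, as the values above show.

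Cholesterol synthesis (median 0.17, camera adjusted p = 0.0102), glycolysis (0.15, 0.0378) and ribosomal protein genes (0.22, 1.33e-05; 20 of 20 positive) were also higher in sh4 than in sh3, with adjusted p of 0.584, 0.695 and 0.584 with an estimated correlation. The same differences in 18S signal and in the Actb ratio, 2.33 in sh3 and 2.80 in sh4, stood beside these lists. The cholesterol call was lost without sh3 replicate 2 (camera adjusted p = 0.202) or sh4 replicate 1 (0.155), and the glycolysis call without the same arrays (0.485 and 0.44); the cholesterol median was 0.08 without sh3 replicate 2, and the glycolysis median 0.27 without sh3 replicate 1, 0.25 without sh4 replicate 2 and 0.09 without sh4 replicate 1. The ribosomal call was lost without sh4 replicate 2 (median 0.14, camera adjusted p = 0.0751), and its median was 0.12 without sh3 replicate 1. Both it and the glycolysis call were lost with quantile normalization (camera adjusted p = 0.148 and 0.193), the cholesterol and glycolysis calls with the mean of probe sets (0.0878 and 0.193) or without probe sets that may cross-hybridize (0.0575 and 0.159), and the glycolysis call without a trend (0.0641). With the block 13 ribosomal genes were higher in sh4 adjusted over the list alone. The number of lists was 5, and 8 without sh3 replicate 1, with ATF4 (camera adjusted p = 0.0152), trophectoderm (0.0152) and neuroectoderm genes (0.00631). Neuroectoderm genes also passed without a filter (camera adjusted p = 0.00459) or sh4 replicate 2 (0.0178), germline genes without sh4 replicate 2 (0.0178), and primed epiblast genes without sh3 replicate 2 (0.0143) or sh4 replicate 1 (0.0288). No single gene passed in this contrast, a count of 0 by limma with a smallest adjusted p of 0.192, against 774 with an unadjusted p under 0.05; limma without a trend also gave 0. With the block 53 passed by limma, 22 higher and 31 lower in sh4. Given as values, the proteoglycan gene Srgn read 136 in sh3 and 685 in sh4 (log2 2.22, SE 0.26). Cubn (1.62), Col4a1 (1.01), the chromatin protein gene Hmga2 (0.91) and Vegfc (0.77) were higher in sh4 on the log2 scale. The melanosome gene Mreg read 8063 in sh3 and 3845 in sh4 (log2 -1.06), and Ssr1 (-0.95), Ptpmt1 (-0.90), Dnajc3 (-0.83), Ap1m2 (-0.81) and Pgrmc1 (-0.61) were lower in sh4. Nr2f2 read 14.1 in sh3, below the 27.8 of an absent control, and 107 in sh4, and its difference was 1.13 with a pseudocount of 64 and 2.87 with 1. All 12 but Nr2f2 (adjusted p = 0.064) passed with the block, with adjusted p from 0.00112 for Srgn to 0.0237 for Vegfc by limma.

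**Figure D4:**
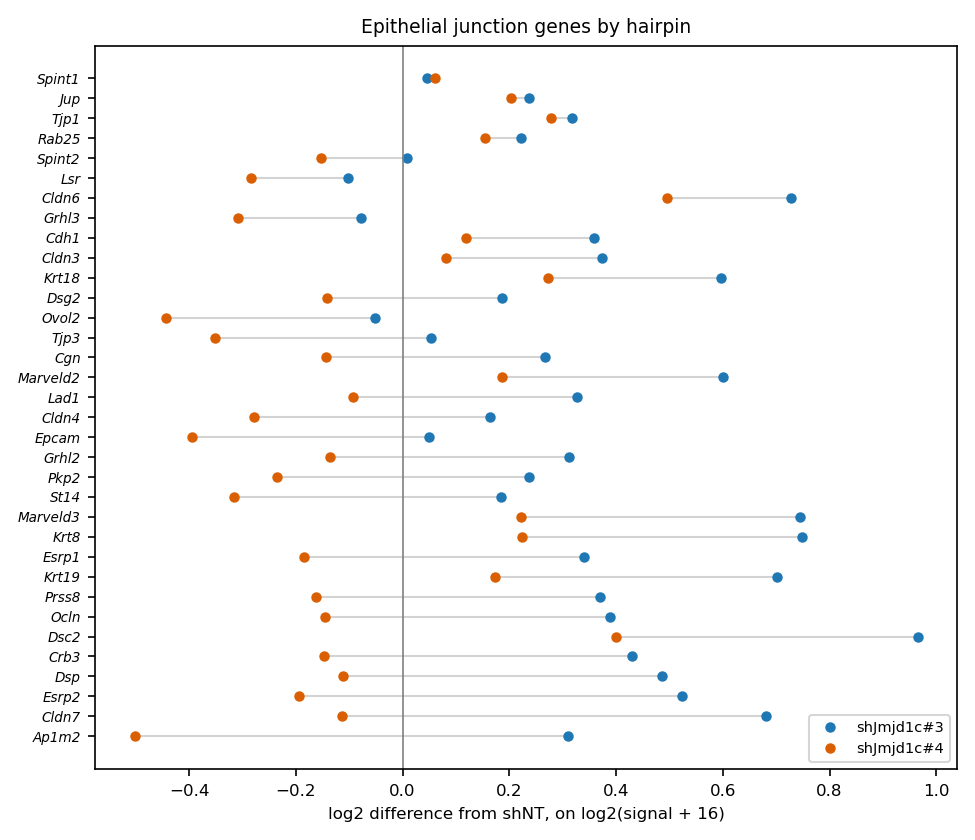
Log2 difference from shNT of the 34 epithelial junction genes in sh3 and in sh4, with a line joining the 2 values of each gene. In 33 of the 34 genes the sh4 value lay below the sh3 value, and the medians were 0.32 and -0.14.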

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

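The test of a graded knockdown was chosen after the result was seen. The other tests in this part were set out before, but the feeder test's condition on dim transcripts was not part of what was set out.

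Mesenchymal genes were higher in the knockdown mean, with a median of 0.64 on the log2 scale over 25 genes (adjusted p = 0.139 by camera with an estimated correlation), and feeder fibroblast markers were higher with them. Scaling of the arrays and 1 control array standing apart were argued against only for the call by camera with the preset correlation. Its largest adjusted p was 1.04e-10 under quantile normalization or median centring and 9.63e-07 without either control. With an estimated correlation the list was not past the threshold by camera (adjusted p = 0.139). With 1 control array left, the test cannot exclude correlated genes moving together on that array, so it does not settle that explanation. Carry-over of feeder fibroblasts stays open. The rule set out for it was that a median change of 6 fibroblast transcripts at or above that of the list points to carry-over. The median of Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn was higher by 0.232 (SE 0.461), so the rule pointed to carry-over. The difference lay within its SE, though, and 5 of the 6 had a control array below 27.8, where a log2 change depends on the pseudocount. That limit, not part of the rule, was the highest reading of an absent control, on a sh3 array, against 8.90 and 5.62 on the controls. The test was therefore taken not to decide. Col1a1 read 39.5 in control and 65.6 in knockdown arrays, and of the 6 only Postn was lower, at 31.6 and 22.3. Controls 1 and 2 were apart for Col1a1, at 5.88 and 73.2, against 53.1 to 86.7 in the knockdown arrays. For Col1a2 they read 52.1 and 175.8, against 118 to 239. Control 2 thus lay within the knockdown range for both genes, while for Col3a1, Dcn and Lum both controls lay below all knockdown arrays. In the control cells 11 of the 15 markers lay above the filter signal, the labels describe gelatin culture, and puromycin selection would remove feeders without resistance. A change in the stem cells themselves with the knockdown, which the design names, also stays open and was not tested.

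Epithelial junction genes differed between the hairpins, with a median of -0.4304 for sh4 minus sh3 and an adjusted p of 1.56e-15 by camera (adjusted p = 0.261 with an estimated correlation). Scaling was argued against only for the call with the preset correlation, by a largest camera adjusted p of 3.4e-15 under both scalings. The same holds for 1 array standing apart, with a largest camera adjusted p of 7.91e-09 without each knockdown array. With 1 array of a hairpin left, the test cannot exclude correlated genes moving together on that array. Deeper knockdown by sh4 in a graded response would need the list to move 1 way from control through sh3 to sh4, and it did not: the medians were 0.32 in sh3 and -0.14 in sh4. The graded explanation still stays open, because the opposite difference had an adjusted p of 0.261 by camera with an estimated correlation. A deeper knockdown by sh4 was itself not shown. For sh4 minus sh3, Jmjd1c probe set 1426900_at was at -0.36 (adjusted p = 0.946 by limma), and 1448049_at and 1439998_at were at 0.05 and 0.10. A candidate explanation that was not tested is an effect of 1 hairpin's sequence on other transcripts.

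Endoderm genes differed between the hairpins too, with a median of 0.2908 for sh4 minus sh3 and an adjusted p of 0.000211 by camera (adjusted p = 0.261 with an estimated correlation). Cholesterol synthesis genes had a median difference of 0.171 (camera adjusted p = 0.0102), glycolysis and hypoxia genes of 0.151 (0.0378) and ribosomal protein genes of 0.223 (1.33e-05), with adjusted p of 0.584, 0.695 and 0.584 with an estimated correlation. Outside the named genes, 4161 probe sets with no or several gene symbols were tested, and 1 was higher in the knockdown mean and 0 lower by limma; with the replicate number as a block 49 were higher and 22 lower. The probe set called without the block, 1438989_s_at, read 46.8 and 37.7 in the control arrays and 223 and 174 in sh3 and 325 and 397 in sh4 (log2 2.28, SE 0.23, adjusted p = 0.0245).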

How the results depend on the processing

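The test of every probe set by itself was chosen after the data were seen. Across all alternatives, tests of single genes gave the same call 2100 times, lost it 353 times and gained it 56 times, with 0 reversals of a call. List tests gave the same call 1933 times, lost it 165 times, gained it 28 times and turned 3 times. A result not called in either setting counted as the same call even where its sign turned, as for Actb (-0.20, and 0.07 without control 2). Where a value moved, the cause was not tested unless stated. Counts of called genes are given for the knockdown mean (92), sh3 (9), sh4 (46) and both hairpins (7). Without a filter they were 36, 0, 21 and 0, and with the mean of a gene's probe sets 34, 0, 27 and 0. Without an intensity trend they were 0, 0, 6 and 0 by limma, with 1499 genes at an unadjusted p under 0.05 in the knockdown mean. With a pseudocount of 1 or a 60th percentile filter sh3 and both hairpins fell to 0, and with only the 4 arrays compared sh3 fell to 0; in these settings 1022 to 1543 genes had an unadjusted p under 0.05 in sh3. Without probe sets ending in _s_at or _x_at the knockdown mean had 59 calls, and with every probe set tested by itself 41. The 5 lists that differed between hairpins became 3 with quantile normalization, with the mean of probe sets and without _s_at and _x_at probe sets. Lists past the threshold were 0 in each contrast by camera with an estimated correlation, and 5, 6, 7 and 1 by fry in the knockdown mean, sh3, sh4 and their difference. Other settings kept these counts within 1.5 times.

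Leaving out 1 array gave 4–43 calls in the knockdown mean, 0–1 in sh3, 3–39 in sh4 and 0–1 in both. It gave r of 0.545–0.783 between hairpins, 3313–6527 genes without overlap and 4–8 lists between hairpins. An arm left with 1 array has fewer samples, and its spread is taken from the other groups. The ribosomal median in the knockdown mean ran from -0.32 to 0.0729, in sh4 from -0.216 to 0.172, and the glycolysis median in sh3 from -0.193 to 0.146; the direction turned without control 2, control 2 and control 1.

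With a replicate block the counts were 710, 435, 622 and 234, with 53 genes between the hairpins, and Jmjd1c probe set 1448049_at (0.90) reached an adjusted p of 0.0127 by limma. Values with the block rest on a pairing inferred from the same arrays. Lists past the threshold by camera were 14, 17, 14 and 5 in the knockdown mean, sh3, sh4 and their difference, and by fry 11, 0, 9 and 0. Beside the calls given with the results, the block changed no other call of a list by camera and ended the call of no named gene.

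Signal over background limits the dim genes: 9 of 71 rises began below the filter signal of 40.12, and their folds shift with the pseudocount. An absent control read up to 8.90 on the control arrays and up to 27.8 on the knockdown arrays.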

Other observations

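The test on Jmjd1c probe sets and the test of gene families were chosen after the data were seen.

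Collagen genes as a family were higher in the knockdown mean. Among 143 families of at least 10 genes with a shared symbol stem, the Col family of 27 genes had 23 positive values and a median of 0.56 on the log2 scale (camera adjusted p = 1.01e-05; adjusted p = 0.986 with an estimated correlation), and 2, Col3a1 and Col4a1, rose over all genes by limma. Fibril-associated Col12a1 (log2 1.75) and Col8a1 (log2 1.69), a short-chain collagen, were not past the threshold and were chosen after their values were seen. With the replicate number as a block 6 collagen genes rose, these 2 included (adjusted p = 0.0212 and 0.018 by limma), and Col8a1 was at 1.12 without control 1. The median was 0.52 with quantile normalization and 0.54 with median centring, and 0.52 over the 23 members that are not feeder markers.

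Krüppel-like factor genes, which include Klf2, Klf4 and Klf5 of the naive pluripotency network, were lower as a family. Of 16 genes 4 were positive and the median was -0.33 (camera adjusted p = 0.0254; adjusted p = 0.986 with an estimated correlation), with 0 past the threshold by limma. The median was -0.32 with quantile normalization and -0.35 with median centring. Klf2 was at -0.68, Klf4 at -0.55 and Klf5 at -0.49, while Klf6 was at 0.56 and Klf7 at 0.47, all 5 chosen after their values were seen. With the block 2 rose, Klf6 and Klf7 (adjusted p = 0.00769 and 0.0366 by limma), and 3 fell, Klf2 and Klf4 among them (0.00116 and 0.00547), while Klf5 had an adjusted p of 0.0656. Without control 1 Klf6 was at 0.36 and Klf5 at -0.81, and without control 2 Klf5 was at -0.16. The Rpl and Rps families passed with the block too (camera adjusted p = 0.0492 and 0.017; adjusted p = 0.988 for each with an estimated correlation).

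The Jmjd1c probe sets moved apart: 1448049_at and 1439998_at had higher values in the knockdown arrays, 0.90 and 0.73 on the log2 scale, while 1426900_at was lower at -0.46. Scaling of the arrays was argued against, since the smallest ratio of either rise to its SE was 2.92 under both scalings. Labels swapped between control and knockdown arrays stay open, as the probe sets point both ways. A swap would not account for the split itself, since exchanging shNT with either hairpin group leaves the probe sets pointing both ways. A hypothesis that stays open and was not tested is that the probe sets read different transcript forms of the gene, which may respond differently to the hairpins.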
